A study of Mus musculus with 2 samples.

How the data were processed

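Ribosome-protected RNA was sequenced from mouse heart in 2 libraries, 1 labelled GFP and 1 labelled COX8-AGO2. Per the labels' protocols, the frozen material was ground in liquid nitrogen and lysed, the lysate was digested with RNase I, ribosomes were passed over size exclusion columns, and ribosomal RNA was removed with antisense DNA probes and RNase H before small RNA library preparation and sequencing. The recovery of ribosomes over such columns and the digestion both shape which footprints are counted, and ribosomes of mitochondria and of the cytosol need not respond alike.

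The deposited table lists 22063 genes by Ensembl identifier and symbol, with an estimated count and an FPKM value per library, per the file headers. The submitters' processing notes list fastp, Bowtie2, STAR, StringTie 1.3.1 and RSEM, without saying what each was used for. The genome build and annotation are not given in the sources used here. The deposited estimated counts are the authors' values without normalization: 1631 values of the COX8-AGO2 library and 2147 of the GFP library are fractional, and the column totals differ. The deposited FPKM values were scaled by the authors to gene length and library total. The length that count and FPKM imply for the mitochondrially encoded genes differs by at most 0.00085 bases between the libraries. Fractional values arise where a read that fits several genes is divided between them, and the notes do not say how this was done, so values of near-identical copies and of overlapping reading frames are uncertain.

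Estimated counts were rounded to whole reads. Gene names are those of the table, and biotypes came from a RefSeq gene table of assembly GRCm38.p6, matched by symbol for 91.8% of rows; no coordinates are given because the build of the table is not named. In the lists, rows sharing a symbol were summed. Library totals were 21607360 reads (COX8-AGO2) and 45597538 reads (GFP), so a count of 0 allows up to 0.139 and 0.0658 CPM before TMM scaling, taking 3 reads as the limit. TMM factors from edgeR 4.0.16 in R 4.3.3 scaled the libraries, a pseudocount of 0.5 was added for ratios, and each ratio carries an exact conditional binomial (Clopper-Pearson) 95% interval, computed with scipy 1.17.1 in Python 3.11.15. The half-width of that interval on the log2 scale is 0.91 for a gene with 50 reads and 0.22 for the median gene with 802 reads. The reads carry no molecular identifiers as far as the labels say, so intervals and floors cover counting error only.

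With 1 library per group there is no replicate check, and no significance test between the groups was run. Explanations in the closing section were weighed by comparing values within the table, with 1 bootstrap range (10000 draws over genes) for the difference between the medians of interferon genes and immune cell markers. Genes with at least 50 reads summed were counted as apart at a ratio of at least 2-fold with an interval that excludes 1, and list members at 1.5-fold by the same rule. The lists, 42 in number, were fixed before the data were examined, and 96.8% of their entries are in the table. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries, and was said to stand apart in the top or bottom 2.5% of them. Named genes were, by a rule fixed in advance, Ago2 and the 13 mitochondrially encoded genes, the 12 higher and 12 lower protein-coding genes with at least 100 reads whose interval lies farthest from 1, leaving out placeholder symbols, and in each list the most read, highest and lowest member with at least 100 reads. Further list members were named as examples, or because 5 or fewer were apart, after their values were seen.

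On simulated counts for 11703 genes drawn from these libraries' means and totals for COX8-AGO2 over GFP, 95.4% of the intervals held the true ratio, 7 unchanged genes came out at least 2-fold apart, and 100% of the genes made 3-fold higher were recovered. These were Poisson counts, with no spread between animals or preparations and with like mitochondrial shares in both libraries. Interval coverage was measured with the true library totals, not with TMM factors. The 7 genes thus reflect counting error alone and give no rate of false calls for the real libraries. Alternatives were scaling by total reads, by DESeq2 1.42.0 median of ratios, by upper quartile and by TMM without mitochondrially encoded genes, the deposited FPKM as input, pseudocounts of 0 and 2, minimums of 10, 200 and 1 reads, a 1.5-fold threshold, protein-coding genes alone, other denominators of the mitochondrial share, and unmatched or coarser-matched random lists. After the data were seen, 2 gene lists and 1 alternative for the mitochondrial share were added. Translational efficiency could not be computed, since the table holds no RNA values.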

Results

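Ribosome footprints, the stretches of messenger RNA that translating ribosomes shield from nuclease, were counted per gene in mouse heart. The series holds 2 libraries. The COX8-AGO2 library came from heart overexpressing COX8-AGO2, and the GFP library from heart given GFP, the control. Ago2 is an Argonaute protein that binds microRNAs, and the leader of a COX8 subunit of cytochrome c oxidase is commonly used to send proteins into mitochondria. The labels do not describe the construct and do not say whether the animals were diabetic. The COX8-AGO2 library held 21607360 gene-assigned reads, with reads on 14311 of the 22063 genes listed, and the GFP library held 45597538, with reads on 14917. The 10 genes with the most reads took 39.2% of the COX8-AGO2 library and 25.7% of the GFP library. Each group has 1 library and there are no replicates, so no difference below could be set against the spread between animals and no p-value is given. Ratios are of the COX8-AGO2 library over the GFP library after TMM scaling, intervals are exact 95% binomial intervals that cover counting error only, and every statement describes these libraries.

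Ago2 itself, reported first because it checks the labels, was 4.90-fold higher in the COX8-AGO2 library (interval 4.56 to 5.27), with 2105 reads against 1171 in the deeper GFP library. Its identifier in the table is ENSMUSG00000036698. The sequence of the construct is not given, so how far its reads count towards Ago2 is not known, and endogenous Ago2 cannot be separated from it. Of the 19 genes of the microRNA machinery with enough reads, only Ago1 and Ago2 were at least 1.5-fold higher and none was that far lower. Ago1 was 1.60-fold higher (1.24 to 2.05) on 103 against 176 reads. Ago3 and Ago4 had log2 ratios of 0.06 and 0.13, and Tnrc6b, which encodes an Argonaute partner, had the lowest, -0.42.

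The title of the series concerns translation of mitochondrial genes, which the footprints on the 13 protein-coding genes of mitochondrial DNA address. These genes held 38.3% of all gene-assigned reads in the COX8-AGO2 library (exact Clopper-Pearson interval 38.33% to 38.37%) and 16.2% in the GFP library (16.24% to 16.26%), a ratio of 2.36 that needs no scaling factor. All 13 had a ratio above 1 after TMM scaling, 12 were at least 1.5-fold higher and 9 at least 2-fold higher, with a median of 2.97-fold. Scaling by total reads kept 12 of the 13 above 1, mt-Atp6 being the exception with a log2 ratio of -0.02. This alternative shifts every log2 ratio by -0.37 and puts the median log2 ratio of the 13 genes at 1.20 in place of 1.57.

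The 13 genes differed widely among themselves. Among the cytochrome c oxidase subunits, mt-Co3 was 9.97-fold higher (9.94 to 10.00), passing from 1.55% of the GFP library to 11.96% of the COX8-AGO2 library, while mt-Co1 was 1.93-fold higher and mt-Co2 1.67-fold higher. The cytochrome b gene mt-Cytb was 3.33-fold higher. All 7 complex I genes were at least 1.5-fold higher, from mt-Nd6 at 1.68-fold to mt-Nd1 at 3.87-fold and mt-Nd4l at 10.5-fold. The most read of them, mt-Nd5, was 2.97-fold higher on 575725 against 528851 reads. The ATP synthase gene mt-Atp8 was 30.6-fold higher (30.2 to 30.9), on 334380 against 29821 reads, and its neighbour mt-Atp6 was 1.27-fold higher (1.26 to 1.28). The reading frames of mt-Atp8 and mt-Atp6 overlap, as do those of mt-Nd4l and mt-Nd4, so how reads were divided within each pair is uncertain. The overlaps need not be alike in length, and their lengths were not measured here. How much of either difference within a pair a division of reads could explain is therefore not known. With the reads of each pair summed, mt-Atp8 and mt-Atp6 were 3.44-fold higher and mt-Nd4l and mt-Nd4 were 4.73-fold higher.

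**Figure D1:**
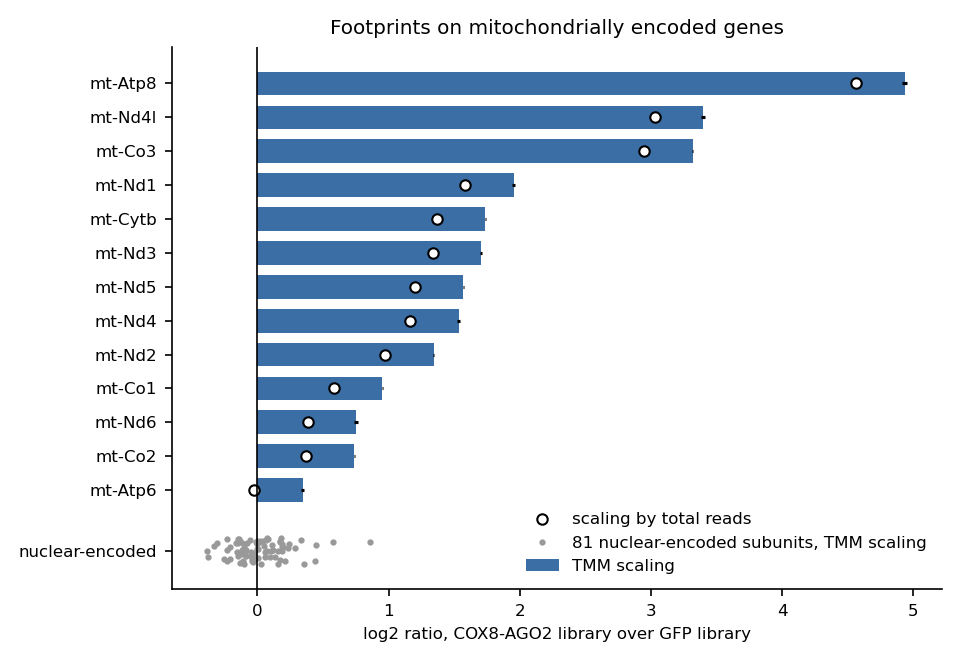
Bars give the log2 ratio of the COX8-AGO2 library over the GFP library for each of the 13 mitochondrially encoded genes after TMM scaling, with the exact 95% counting interval as a black line that is mostly narrower than the bar's edge. Open circles give the ratio after scaling by total reads, which puts mt-Atp6 at -0.02, and grey points, spread vertically for legibility, give 81 nuclear-encoded subunits of the same complexes, which lie between -0.39 and 0.86.

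Nuclear-encoded subunits of the respiratory chain and ATP synthase did not show this difference. The median log2 ratio of the 81 on the lists used here was -0.0048 and their range was -0.39 to 0.86. Of these, 1 was at least 1.5-fold higher and 0 lower. That gene was Cox8a, 1.82-fold higher (1.75 to 1.88) on 5365 against 8048 reads, whereas Cox8b, the isoform typical of heart and muscle, had a log2 ratio of 0.06. Cox4i2, a complex IV subunit that is not on these lists, was at least 1.5-fold lower. Reads from a COX8 leader in the construct could not be separated from those of endogenous Cox8a. Ndufs2 of complex I, Sdha of complex II and Cox4i1 of complex IV, the most read of their groups, had log2 ratios of 0.00, -0.10 and -0.04. The medians of the nuclear lists were -0.03 for complex I, 0.00 for complexes II and III, 0.02 for complex IV and -0.04 for ATP synthase, and none stood apart from random lists matched on expression. Scaling by total reads puts these 4 medians between -0.41 and -0.35. Among the 81 listed genes, Uqcr11 of complex III had the highest ratio outside complex IV, 0.57, and Ndufa12 had the lowest, -0.39.

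The machinery that makes and imports mitochondrial proteins shifted little. Mitochondrial ribosomal proteins had a median log2 ratio of 0.12, above all or nearly all matched random lists (percentile 100), but 0 of the 79 were at least 1.5-fold apart, with Mrpl34 highest at 0.55 and Mrps36 lowest at -0.29. Mitochondrial aminoacyl-tRNA synthetases, which load amino acids onto mitochondrial tRNAs, had a median of 0.17 (percentile 99.7) and also 0 of 20 at least 1.5-fold apart. Protein import and protease genes had a median of 0.17 (percentile 100). Of these 31 genes, 2 were at least 1.5-fold higher, the outer membrane translocase subunit Tomm5 at 1.72-fold and the small chaperone Timm8b at 1.51-fold. Mitochondrial translation and transcription factors, Tufm and Tfam among them, had a median of 0.03 (percentile 84.2), with 0 of 26 at least 1.5-fold apart. Cytosolic ribosomal proteins had a median of 0.08 (percentile 100), with 0 of 78 that far apart. The random lists were matched on expression only, and coding length was not checked for these 5 lists. Nuclear genes with an implied length under 400 bases, 685 in number, had a median log2 ratio of 0.062. All 5 medians are below 0 under scaling by total reads and with the deposited FPKM, which is also scaled to the library total. The percentiles stay on the same side there, but the random lists carry the same shift, so the percentiles could hardly change.

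Across the table, 11713 genes had at least 50 reads summed over both libraries, and 89.5% of them lay within 1.5-fold. By the rule fixed in advance, a ratio of at least 2-fold and an interval that excludes 1, 175 genes were higher and 142 lower in the COX8-AGO2 library. Under scaling by total reads the split was 78 higher and 461 lower, so the balance between directions depends on the scaling. TMM without mitochondrially encoded genes gave 175 and 142 again. Total reads include the mitochondrially encoded reads, 38.3% of the COX8-AGO2 library and 16.2% of the GFP library. That larger share by itself lowers every nuclear ratio under scaling by total reads. The same shift moves list members towards lower values, and the counts of list members given here hold for TMM scaling unless stated. Of the 41 gene lists fixed before the data were examined that had at least 2 members measured, 12 had a median in the top 2.5% of 10000 random lists matched on mean expression and 3 in the bottom 2.5%. By chance 2.05 in total would be expected if the genes within a list varied independently. Members of a list can vary together between any 2 hearts, so the comparison with 2.05 is no test.

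**Figure D2:**
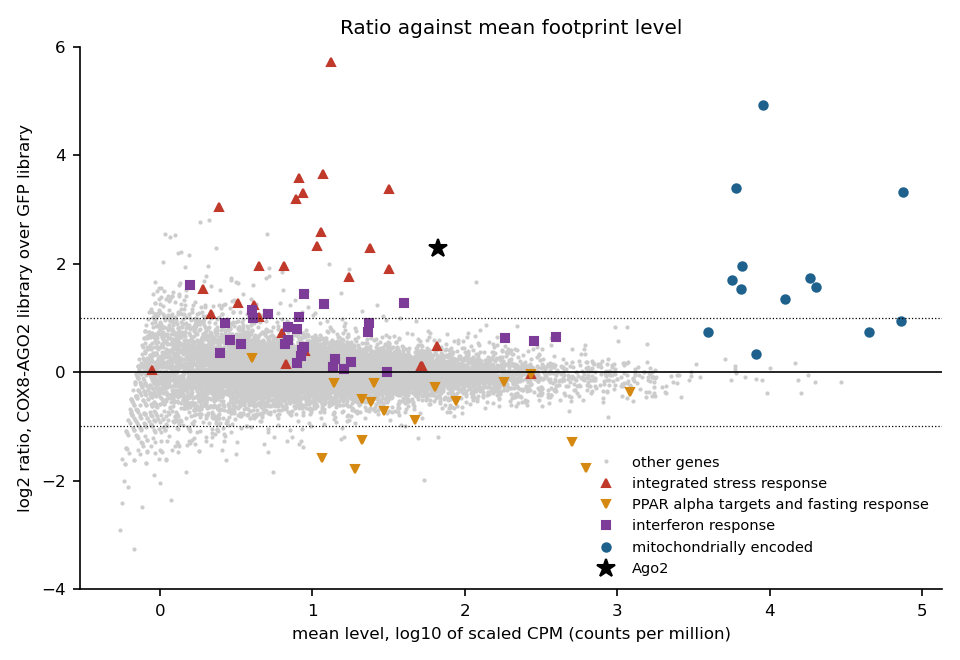
Each point is a gene, with its mean level in scaled CPM on a log10 axis against its log2 ratio of the COX8-AGO2 library over the GFP library after TMM scaling, and dotted lines mark 2-fold. Of the genes with at least 50 reads, 11705 are drawn and 8 with no read in 1 library are left out; the mitochondrially encoded genes lie at the right, above 0, and most integrated stress response genes lie above the upper dotted line.

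Genes of the integrated stress response, the programme that the transcription factors Atf4, Atf5 and Ddit3 run when translation initiation is restrained, were higher as a group. Of 27 measured genes, 20 were at least 1.5-fold higher, 0 lower and 7 neither, and the median log2 ratio was 1.91 (percentile 100). Mthfd2, a mitochondrial enzyme of the folate cycle, was 52.7-fold higher (36.0 to 83.9) on 493 against 25 reads. Asparagine synthetase (Asns) was 12.6-fold higher (10.0 to 16.0), the secreted stress factor Gdf15 11.9-fold (9.13 to 15.9), Atf5 10.4-fold (9.12 to 11.9) and Trib3 9.87-fold (7.75 to 12.8). Phgdh and Pycr1, enzymes of serine and proline synthesis, were 9.20-fold and 8.27-fold higher, and the amino acid transporter Slc7a5 was 5.99-fold higher. Atf4 was 3.77-fold higher (3.42 to 4.16) and Chac1 4.91-fold higher. Fgf21, a hormone released under mitochondrial stress and fasting, had 55 reads against 0, at least 39.3-fold higher by the lower end of its exact interval (50.0-fold against a floor of 3 reads). Vldlr was the most read member and had the lowest ratio, -0.04. Atf4, Chac1 and Fgf21 were picked as examples after their values were seen. Under scaling by total reads 19 genes of the list were at least 1.5-fold higher. Chaperones of the endoplasmic reticulum and heat shock response, by contrast, had a median of -0.08 (percentile 26.2) and 0 of 25 at least 1.5-fold apart, although under scaling by total reads 10 were that far lower (percentile 27.3).

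Targets of PPAR alpha and genes of the fasting response were lower as a group, with a median log2 ratio of -0.51 (percentile 0), 7 of 18 at least 1.5-fold lower (12 under scaling by total reads) and 1 higher. The exception was Fgf21, which is also on the stress response list. Adipocyte and Schwann cell markers had the same median, -0.51, on 7 genes. The lipoprotein lipase inhibitor Angptl4 was 3.42-fold lower (2.92 to 4.06), and Pdk4, the kinase that shuts off pyruvate dehydrogenase, was 3.39-fold lower (3.30 to 3.49) on 5417 against 50080 reads. Hmgcs2, the rate-limiting enzyme of ketone synthesis, was 3.00-fold lower, Txnip, an inhibitor of glucose uptake, 2.45-fold, the thioesterase Acot1 2.39-fold and the uncoupling protein Ucp3 1.84-fold. Fatty acid uptake and oxidation genes shifted the same way by less. Their median was -0.21 (percentile 0.03), and 29 of 32 had a ratio below 1, although none was 1.5-fold apart. The lowest was Decr1 at -0.52, the most read was lipoprotein lipase (Lpl) at -0.38, and the highest was Fabp3 at 0.11. Scaling by total reads lowers this list's median to -0.58 and puts 16 of its genes at least 1.5-fold lower.

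Other parts of energy metabolism showed no list that stood apart. Glucose uptake and glycolysis genes had a median log2 ratio of -0.09, with Pgam1 at least 1.5-fold higher (1.58-fold) and the insulin receptor substrate Irs2 lower (2.42-fold, 1.96 to 3.06). Genes of the TCA cycle and pyruvate dehydrogenase had a median of -0.06 and 0 of 28 at least 1.5-fold apart. Branched-chain amino acid and ketone catabolism had a median of -0.12, with the ketone body enzyme Bdh1 1.56-fold higher. Antioxidant genes had a median of 0.02, with Ucp2 and Ucp3 at least 1.5-fold lower. Proteasome genes had a median of -0.04, autophagy and mitochondrial dynamics genes -0.01, with only the muscle atrophy ligase Fbxo32 at least 1.5-fold lower (1.68-fold), and cytosolic translation factors -0.05, with only Eif2s2 at least 1.5-fold higher.

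Interferon response genes were higher as a group. All 30 measured had a ratio above 1, 17 were at least 1.5-fold higher and 0 lower, and the median log2 ratio was 0.61 (percentile 100). The ubiquitin-like protein Isg15 was 2.74-fold higher (2.28 to 3.28) on 245 against 244 reads, and the most read member, beta-2-microglobulin (B2m), was 1.57-fold higher (1.53 to 1.61). Stat1 had the lowest ratio, 0.01. Macrophage markers were also higher, with a median of 0.27 (percentile 99.98) and all 19 above 1. Their median is however below 0 under scaling by total reads and with the deposited FPKM, which is also scaled to the library total. Of these, 4 were at least 1.5-fold higher, Cx3cr1, Tyrobp, Cd68 and Fcgr1, the last with the highest ratio at 1.62-fold. Lyz2, the most read, was 1.26-fold higher. Lymphocyte and neutrophil markers had a median of 0.14 (percentile 87.0), with the neutrophil proteins S100a8 and S100a9 lower, S100a9 by 2.31-fold on 19 against 122 reads. Under scaling by total reads, 8 interferon genes and 0 macrophage markers were at least 1.5-fold higher.

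Erythroid and platelet markers, which report blood left in the tissue, had a median log2 ratio of 0.74 (percentile 100), with 5 of 9 at least 1.5-fold higher: Pf4, Hba-a1, Hbb-bt, Itga2b and Hba-a2. Under scaling by total reads only 1 of them was that far higher. Hba-a2 was 3.18-fold higher, but it can share reads with the near-identical Hba-a1, which was 1.78-fold higher, and the most read globin, Hbb-bs, was 1.44-fold higher. Adipocyte and Schwann cell markers were lower, with a median of -0.51 (percentile 0.800) and 3 of 7 at least 1.5-fold lower: Scd1 on 85 against 398 reads, Car3 on 7 against 58 and Mbp on 6 against 54. Endothelial markers had a median of -0.05, fibroblast and matrix genes 0.02, and smooth muscle and pericyte markers -0.02, the last with Myl9 and Cnn1 at least 1.5-fold higher. Atrial and conduction markers had a median of 0.09, with Msln, Myl4 and Wt1 higher and Nppa and Stard10 lower, and skeletal muscle markers -0.06, with Atp2a1 higher and Tnni2 lower.

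Genes of the contractile apparatus had a median log2 ratio of -0.08 (percentile 34.7). The most read, the myosin heavy chain Myh6, was 1.14-fold lower on 522705 against 1622955 reads. Of the 26, Myom2, Mypn and Xirp1 were at least 1.5-fold lower, Myom2 by 1.77-fold (1.74 to 1.81), and Myh7b was 1.62-fold higher. Calcium handling and ion channel genes had a median of -0.14 (percentile 6.64), with 1 of 23 at least 1.5-fold apart, the inward rectifier Kcnj2, which was 1.99-fold lower (1.81 to 2.19). The calcium pump Atp2a2 had a log2 ratio of -0.39. Fetal and stress genes of cardiomyocytes went both ways, with a median of -0.04. Nppb, which encodes B-type natriuretic peptide, was 1.82-fold higher, and Gdf15, given above, was the other one higher. The atrial peptide gene Nppa was 1.58-fold lower, the matricellular gene Ccn2 2.30-fold lower, the metallothionein Mt2 2.33-fold lower and Lcn2 2.09-fold lower on 11 against 65 reads.

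Immediate early genes had a median log2 ratio of -0.13 (percentile 5.15), with Myc 3.60-fold higher (2.88 to 4.51), Atf3 2.42-fold higher, and Nr4a3, Nr4a1, Btg2, Junb and Ccn1 at least 1.5-fold lower. Clock genes had a median of -0.03 with 1 of 18 at least 1.5-fold apart, Arntl, which was 1.53-fold lower on 73 against 306 reads, and 7 of 18 under scaling by total reads, all lower. The Y-linked genes Uty, Ddx3y, Eif2s3y and Kdm5d were read in both libraries, with ratios from -0.24 for Uty to -0.13 for Kdm5d. Replication-dependent histones and cell cycle genes had a median of 0.36 (percentile 99.4), with H1f3 and Cdk1 at least 1.5-fold higher, and a median just below 0, -0.0072, under scaling by total reads. Nuclear noncoding RNAs that would report RNA quality are not listed in the table.

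**Figure D3:**
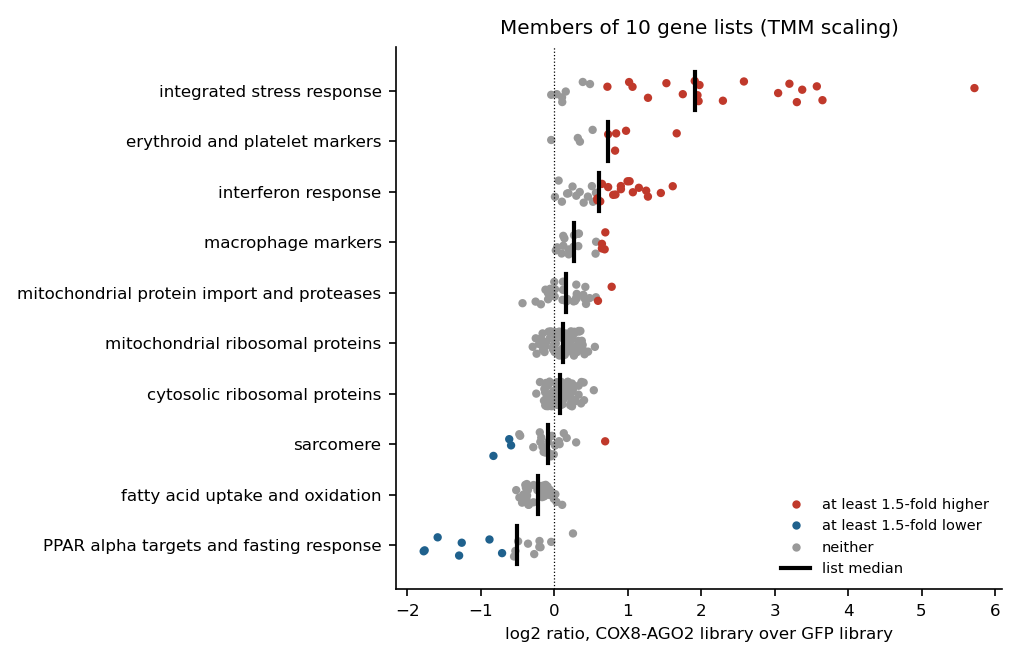
Each point is a member of 1 of 10 gene lists, placed at its log2 ratio of the COX8-AGO2 library over the GFP library after TMM scaling and spread vertically for legibility, with black lines at the list medians; Fgf21, with 0 reads in the GFP library, is not drawn but counts in the medians. Stress response members reach 5.72 (Mthfd2), fasting response members reach -1.78 (Angptl4), and ribosomal protein lists lie close to 0; scaling by total reads shifts every point by -0.37.

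Among single genes with at least 100 reads, the 12 with the highest lower bound were 3 mitochondrially encoded genes (mt-Atp8, mt-Nd4l and mt-Co3), 8 stress response genes and Ago2. The 12 at the other end included the PPAR alpha and fasting genes Pdk4, Angptl4, Hmgcs2, Txnip and Acot1, and also Kdm1a, a histone demethylase, which was 3.97-fold lower (3.59 to 4.41) on 413 against 4474 reads. Ccn2, Mt2, the transcription cofactor Arid5b (2.60-fold), the kinase Sbk3 (5.11-fold on 7 against 104 reads) and the macrophage membrane gene Ms4a6d (2.77-fold) were lower too. Rnaset2a had 0 reads against 1509, at least 149.9-fold lower by the end of its exact interval nearest 1 (185-fold against a floor of 3 reads), but its near-identical copy Rnaset2b was 1.37-fold higher, and with both summed the ratio was 1.01 (0.959 to 1.06), so the difference for Rnaset2a is uncertain.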

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

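No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. The scaling, the read minimum, the fold threshold and the input values all moved counts of genes. Scaling by total reads shifts every log2 ratio by -0.37, while median of ratios and TMM without mitochondrially encoded genes gave 175 higher and 142 lower genes as in the main setting. The log2 ratio of Ago2 was 1.92 with total scaling and also 1.92 with the deposited FPKM, against 2.29. Genes at least 2-fold higher numbered 78 with total scaling, 126 with the deposited FPKM, 367, 63 and 494 with minimums of 10, 200 and 1 reads, and 586 at 1.5-fold. Genes at least 2-fold lower numbered 461 with total scaling, 631 with the deposited FPKM (where no interval applies), 259, 39 and 259 with those minimums, and 496 at 1.5-fold. Fewer or more genes pass the minimums by construction. The deposited FPKM is scaled to the library total, so its ratios share the shift of total scaling, and its counts lack the interval rule. What else moved the FPKM counts was not tested. The mitochondrially encoded share was 38.5% (COX8-AGO2) and 16.3% (GFP) of protein-coding genes, 37.7% and 14.1% of FPKM, and 43.8% and 19.8% without the 10 most read nuclear genes. Without mt-Co3, mt-Atp8 and mt-Nd4l, an alternative chosen after seeing the data, it was 27.9% and 14.8%. Of the list percentiles, 513 comparisons stayed on their side. Those between scalings say little, since a change of scaling shifts lists and random lists alike. With at least 200 reads, adipocyte and Schwann cell markers came to the 2.88th percentile, atrial and conduction markers to 0.300 and immediate early genes to 0.390, with fewer members measured; the cause was not tested beyond that. Of the named gene values, 719 stayed within the counting interval and 294 moved outside it, none of those at least 1.5-fold apart changing sign. Depth limits genes near 50 reads, whose log2 interval is 0.91 wide on either side.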

Other observations

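The tests of tissue share, RNA level, footprint recovery, overlapping reading frames, short mitochondrially encoded frames, time of day, fat tissue, pathways without H2 and histone genes, and differences between animals given here were chosen after the results they concern had been seen. Histone genes of the gene clusters, gathered by symbol after their values were seen, were mostly higher in the COX8-AGO2 library. Of 56 with at least 50 reads, 48 had a ratio above 1, 32 were at least 1.5-fold higher and 0 lower, and the median log2 ratio was 0.64; under scaling by total reads 38 were above 1. H2bc8 was 3.97-fold higher (3.39 to 4.65) and H3c11 3.79-fold higher (2.96 to 4.88). The reads of all 56 summed gave 1.299-fold (1.27 to 1.33), and 1.01-fold under scaling by total reads, since the most read members shifted least. The copies are near-identical, and 6 genes carry the same pair of counts as another, so single members are uncertain. Among the major histocompatibility class I genes, H2-Q6 was 3.73-fold and H2-Q7 2.81-fold higher, though these too are similar copies that can share reads, and the mast cell protease Mcpt4 was 3.44-fold higher on 153 against 121 reads.

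In the pathway annotation deposited with the table, 311 pathways had 15 to 300 measured genes, and 42 had a median in the top 2.5% and 28 in the bottom 2.5% of matched random lists. Fatty acid elongation (-0.24), histidine metabolism (-0.23), ether lipid metabolism (-0.20) and tryptophan metabolism (-0.20) were among the lowest medians. By median PPAR signaling (-0.18, 53 genes) lay above these and above several other pathways outside lipid metabolism. By percentile among matched random lists it lay below them, at 0. Fatty acid elongation was at 0.2, histidine metabolism at 0.7, ether lipid metabolism at 0.05 and tryptophan metabolism at 0.45. The highest medians were those of systemic lupus erythematosus (0.34, with 32 of 86 genes at least 1.5-fold higher), allograft rejection (0.34), graft-versus-host disease (0.32) and autoimmune thyroid disease (0.32). Primary immunodeficiency (0.27), type I diabetes mellitus (0.25), glycine, serine and threonine metabolism (0.23), cell adhesion molecules (0.20) and aminoacyl-tRNA biosynthesis (0.19) were also high. Of the 32 higher lupus genes 30 were the histone copies above, and the higher genes of allograft rejection, graft-versus-host disease, autoimmune thyroid disease and type I diabetes were the same 6 H2 genes. Without H2 genes and these histones the lupus median was -0.007 (31 genes, percentile 56.5) and that of type I diabetes -0.12 (9 genes, percentile 25.9), whereas the other medians stayed at 0.32 to 0.34 on 5 to 7 genes, at percentiles of 91.2 to 92.25. Cox8a had 2411 reads above its scaled GFP level, or 10.1 per base of implied coding length, whereas Ago2 had 1675, or 0.641 per base, a ratio of 15.7; whether reads of the construct's COX8 and AGO2 sequences count towards these genes is not known.

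The first pattern is the larger share of mitochondrially encoded footprints. A larger share of cardiomyocytes or of mitochondria-rich tissue would raise nuclear-encoded respiratory subunits as well, but their median log2 ratio was -0.0048 and that of sarcomere genes -0.08. More mitochondrial RNA with no change in translation per RNA stays open, since the table has 0 columns of RNA values, although an equal rise of every RNA alone would not spread the log2 ratios over 2.58, the span with overlapping pairs summed. Recovery of mitochondrial ribosome footprints that differed between the 2 preparations cannot be told apart from the overexpression with 1 library per group. An effect of COX8-AGO2 on mitochondrial translation, which the title names, may account for the share and was not tested separately.

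The second pattern is the unevenness among the mitochondrially encoded genes. Whether reads of overlapping reading frames were assigned differently in the libraries stays open for mt-Atp8 and mt-Atp6. Their summed log2 ratio of 1.78 lies within the 0.74 to 1.95 of the 8 genes without such an overlap, mt-Co3 left out. A summed ratio must lie between those of its members, here 0.34 and 4.93, and the range is wide and was chosen after the values were seen. Lying inside it therefore does not decide the question. The same holds for mt-Nd4l and mt-Nd4, whose summed ratio of 2.24 lies 0.29 above the range of the 8 genes but inside it when mt-Co3 (3.32) is kept. Better recovery of short reading frames stays open too. The median log2 ratio of 685 nuclear genes with an implied length under 400 bases was 0.062, but cytosolic ribosomes read these. Of the 3 mitochondrially encoded genes that short, mt-Atp8 (4.93) and mt-Nd4l (3.40) overlap a neighbour and lie above the longer genes (0.74 to 1.95, mt-Co3 left out). The lengths of these overlaps were not measured here, so how much of either ratio a division of reads could explain is not known. The third, mt-Nd3, was taken as free of overlap, and its 1.70 lies among the longer genes, but 1 gene does not decide it. The ratio of mt-Co3 has neither a long overlap nor a short frame to account for it and stays unexplained.

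The third pattern is that stress response genes were higher and fasting response genes lower. A trend of the ratio with coding length and expression level was argued against: with the median of genes of like length and level subtracted, the median of the 26 stress response genes with a length went from 1.83 to 1.82, and that of 17 fasting genes from -0.53 to -0.46. A smaller share of fat tissue in the COX8-AGO2 library, since adipocyte markers were lower too, was argued against only for the most read fasting genes. The 4 adipocyte markers with at least 50 reads (Fabp4, Scd1, Cfd and Car3) lacked 0.094 times as many reads as the 18 fasting genes. These markers are among the most abundant transcripts of fat. Most of the missing fasting reads fell on Pdk4 (5417 against 50080 reads) and Txnip (5576 against 37244). The sum therefore says little on less read fasting genes. Fabp4, which is also on the endothelial list, held most of the adipocyte side, with 7729 missing reads in all and 232 without it. Time of day of tissue collection stays open. With TMM scaling 1 of 18 clock genes was at least 1.5-fold apart. With scaling by total reads 7 were, all lower, but that scaling shifts every log2 ratio by -0.37, so these 7 say little on time of day. Arntl (-0.61) and Ciart (0.53) lay on opposite sides, while Per3 was at 0.38 and Dbp at 0.03, both with intervals that include no difference. Per1 (-0.54) and Per2 (-0.56) lay on the side of Arntl. Feeding state or other differences between the animals cannot be told apart from the overexpression with 1 library per group. A stress response to altered mitochondrial translation may be involved, as a hypothesis that these libraries cannot separate from those differences.

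If the stress response seen here is the Atf4 programme, other gene groups it is known to reach might be higher too, and 2 lists were added to test this. Cytosolic aminoacyl-tRNA synthetases lay at percentile 99.98, with a median log2 ratio of 0.20 that is below 0 under scaling by total reads, and 6 of 20 were at least 1.5-fold higher: Yars, Mars1, Cars, Gars, Eprs and Aars. Under scaling by total reads 1 was that far higher and 2 lower. Amino acid transporters outside the stress response list lay at percentile 19.4, with a median of -0.09, Slc1a4 (4.89-fold) and Slc6a9 (2.85-fold) higher and Slc1a5 and Slc36a1 lower. By percentile the first group stood apart from matched random lists and the second did not. The second list leaves out transporters already on the stress response list, such as Slc7a5 (5.99-fold higher). Its percentile therefore covers the remaining transporters only and does not decide whether the programme reaches transporters.

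Interferon genes and immune cell markers differed in size. The 30 interferon genes had a median log2 ratio of 0.61 and the 29 macrophage, lymphocyte and neutrophil markers 0.24, a difference, markers minus interferon genes, of -0.37 (95% bootstrap range over genes -0.67 to -0.22), where genes are not independent replicates.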
